A study of Homo sapiens with 2 samples.

How the data were processed

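RNA sequencing of a human breast cancer cell line, called 468 in the labels and grown in L15 medium with serum, was examined in 2 libraries. One library came from cells in which the antisense RNA THAP7-AS1 was knocked down with a Smart Silencer, a commercial mixture of silencing oligonucleotides, and the other from cells given a negative control (si-NC). Samples were collected after 48 h. The treatment label names the silencer for both samples, and the groups were therefore taken from the genotype label, which separates them.

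Each deposited table gives FPKM per gene for 1 library, per the file headers. The submitters' processing notes name cutadapt, HISAT2 2.0.5 and StringTie and the build hg19; the versions of cutadapt and StringTie, the gene annotation and the strandedness of the libraries are not given in the sources used here. FPKM scales each gene by its length and by the fragments of its library, so that a few abundant genes can shift all others, and StringTie divides reads between overlapping models by estimate. The same 13017 genes were listed for both libraries. A symbol was found for 12746 of them through the table of gene identifiers. GENCODE release 29, which describes another genome build, was used by gene identifier only, for gene types, transcript sequences, lengths and overlaps of exons, and no coordinates are given. It matched 12933 identifiers, of which 12918 are protein-coding, and 84 identifiers had no match.

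The log2 ratio of each gene was computed as log2((knockdown FPKM + 1)/(control FPKM + 1)), so every fold is on the FPKM + 1 scale and understates the change of low genes. Genes with a mean of at least 1 FPKM over the 2 libraries were kept, which left 10925. With 1 library per group there is no replicate check and no test of the groups, and a rule of size, a difference of at least 2-fold, took its place. The genes named are THAP7 and the measured genes around it, then the 15 highest and the 15 lowest ratios among genes at least 2-fold apart with a mean of at least 5 FPKM, and up to 4 members with the largest ratios in either direction of each gene list described. Some list members that this rule takes are not reported here. Small RNA genes were to be left out of the highest and lowest ratios, and 0 of the genes at least 2-fold apart with a mean of at least 5 FPKM were of that kind. For each of 59 gene lists, the median log2 ratio was set against 10000 random lists of the same size matched in 20 bins of mean expression, where at least 5 members were measured. This rank describes these libraries only. These rules, the lists and most alternatives were fixed before the data were examined; the alternatives changed the pseudocount, the filter, the scaling, the fold and the matching of random lists. Matching on 3' UTR length, added later, used the longest annotated 3' UTR of each gene or that of its principal transcripts as GENCODE marks them (APPRIS), with the median where several were marked alike.

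The tables hold no counts. In genes with a single annotated transcript, the lowest values times gene length gathered near 89.7 in the knockdown library and 91.6 in the control library, over 14 and 9 genes. Taken as the value of 1 fragment, these steps correspond to about 11100000 and 10900000 fragments. The window in which they were sought was set after the values had been seen, so this depth is an estimate. At that depth, the counting error of a log2 ratio of FPKM without the added 1 would be about 0.22 for genes with a mean of 1 to 2 FPKM. For genes of at least 100 FPKM it would be 0.029. Adding 1 makes the error smaller for low genes, so 0.22 is not the counting error of the ratios given here. Fragments per gene were reckoned from the length of all its annotated exons, which may overstate them.

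The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated libraries for the knockdown against control comparison, in which 200 of 10932 genes were changed. The 2-fold rule took 16 of the 67 genes changed 2-fold, 59 of the 67 changed 3-fold and 66 of the 66 changed 5-fold. It took 0 of 9477 unchanged genes, a result largely set in advance by the simulated noise. That noise was normal, with an SD near the MAD-based SD (from the median absolute deviation) of the real ratios. The real ratios had an SD of 0.31 and a MAD-based SD of 0.21, so their tails were longer. The 0 is therefore no rate of false calls for the real libraries. A list of 30 genes shifted by 0.2 had a median of 0.093, at percentile 99.3. Of 200 random lists, 9 lay outside the central 95 percent, a share largely set in advance because they were drawn like the lists they were ranked against. An effect of -0.1 planted on genes with 1 word of 7 bases in the 3' UTR put that word lowest of all words. The simulated noise was independent over genes, so lists or words whose genes vary together were not tested.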

Results

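Gene expression was compared between 468 breast cancer cells in which the antisense RNA THAP7-AS1 had been knocked down for 48 h and cells given a negative control, with 1 library per group. No difference below has a replicate check, and each describes these 2 libraries. The FPKM values summed to 213442 in the knockdown library and 213888 in the control library, at an estimated depth of 11100000 and 10900000 fragments. The 13 mitochondrially encoded genes took 14.6% and 15.8% of these sums. FPKM was listed at 0 for 226 genes in the knockdown library and 265 in the control library, 146 of them in both.

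The first comparison concerned the targeted locus on 22q11.21. THAP7-AS1 itself is not analysed here, so its knockdown was not checked from its own level. THAP7 (ENSG00000184436.11_2), a zinc finger gene of the THAP family that overlaps THAP7-AS1 on the opposite strand, was higher in the knockdown library, at 8.38 FPKM against 2.71 in the control library, a log2 ratio of 1.34. Because the strandedness of the libraries is not stated, reads of THAP7 and of its antisense partner cannot be told apart. The adaptor gene CRKL was at 18.03 and 24.49 FPKM, a log2 ratio of -0.42. The log2 ratio was 0.20 for LZTR1, 0.09 for the lipid kinase gene PI4KA, 0.03 for the Mediator subunit gene MED15 and -0.02 for SNAP29. Among 10 measured genes of the THAP family, THAP3 followed THAP7 with 3.53 and 1.86 FPKM, and the family median of -0.01 lay at percentile 37.4 of random lists.

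The second comparison asked which genes differed most between the libraries. Of 10925 genes, 66 were at least 2-fold higher in the knockdown library and 73 at least 2-fold lower, together 1.27%. Another 94.6% of the 10925 genes differed by less than 1.5-fold. The median log2 ratio was 0.02 with an SD over genes of 0.31, and the log2 values of the libraries had a Pearson r of 0.978 across genes, which are not independent replicates. The MAD-based SD of the log2 ratio was 0.25 for genes with a mean of 1 to 2 FPKM and 0.14 for genes of at least 100 FPKM. The counts of 2-fold genes depended on the pseudocount, with 140 higher and 126 lower at 0.1 but 19 and 14 at 5. Without the 1642 genes that share exons with another gene on the same strand, 39 were higher and 45 lower.

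Among the genes higher in the knockdown library, DDIT3, the stress-induced transcription factor CHOP, was at 8.78 FPKM against 1.97, a ratio of 3.30. The F-box gene FBXL14 was at 9.10 against 1.31 FPKM, the phosphatase gene DUSP3 at 13.01 against 3.129 and PAQR4 at 18.9 against 4.93. The splicing factor gene SRSF4 was at 23.1 against 8.20 FPKM, the tropomyosin gene TPM4 at 81.7 against 33.7 and S100A13, a member of the S100 family of calcium-binding proteins, at 61.2 against 21.4. The mitochondrial ribosomal protein gene MRPL34 was at 24.8 against 9.45 FPKM, and TBC1D10B at 7.75 against 2.80. Other members of this group share exons with genes that are listed separately. TOMM6, a subunit of the protein import complex of the outer mitochondrial membrane, was at 70.5 against 6.59 FPKM, while ENSG00000124593, which shares exons with it, was at 3.53 against 8.60. The readthrough gene PPAN-P2RY11 was at 21.1 against 1.37 FPKM, while PPAN was at 24.2 against 41.7 and P2RY11 at 8.24 against 8.10. CS, which encodes citrate synthase, was at 16.9 against 3.73 FPKM, while ENSG00000144785 was at 4.85 against 4.41. TEN1, a telomere gene, was at 12.3 against 4.62 FPKM and TEN1-CDK3 at 2.32 against 3.73. PEDS1-UBE2V1 was at 24.0 against 8.82 FPKM, PEDS1 at 4.78 against 7.32 and UBE2V1 at 35.7 against 37.4.

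Among the genes lower in the knockdown library, the immediate early gene IER2 was at 2.77 FPKM against 33.9 in the control library, a 9.24-fold lower value. NRSN2 was at 2.576 against 15.96 FPKM, a 4.74-fold lower value. GPD1L was at 2.25 against 8.80 FPKM, the vitamin C transporter gene SLC23A2 at 2.24 against 8.65 and the Mediator subunit gene MED29 at 3.04 against 10.9. MAPK1IP1L was at 4.194 against 13.02 FPKM, SLC22A23 at 2.46 against 8.26, and the polarity gene LIN7C at 9.09 against 24.7. GRPEL2, a nucleotide exchange factor of mitochondrial HSP70, was at 2.65 against 8.11 FPKM, and the RNA-binding protein gene RAVER1 at 14.02 against 35.51. The others in this group share exons with another gene. SLC35F6 was at 5.93 against 24.5 FPKM while CENPA, which shares exons with it, was at 8.01 against 7.23, and C7orf25 was at 2.24 against 8.74 while ENSG00000256646 was at 1.60 against 0.086. The genes without a symbol ENSG00000257065, ENSG00000267952 and ENSG00000260342 were at 0.020 against 13.4, 2.14 against 33.2 and 3.78 against 11.4 FPKM. Of the genes that share exons with them, LTV1 was at 63.7 against 58.04 FPKM, PHACTR2 at 5.65 against 4.28, ZNF358 at 24.5 against 12.8, ARL6IP1 at 23.6 against 24.2 and RPS15A at 43.4 against 41.4.

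**Figure D1:**
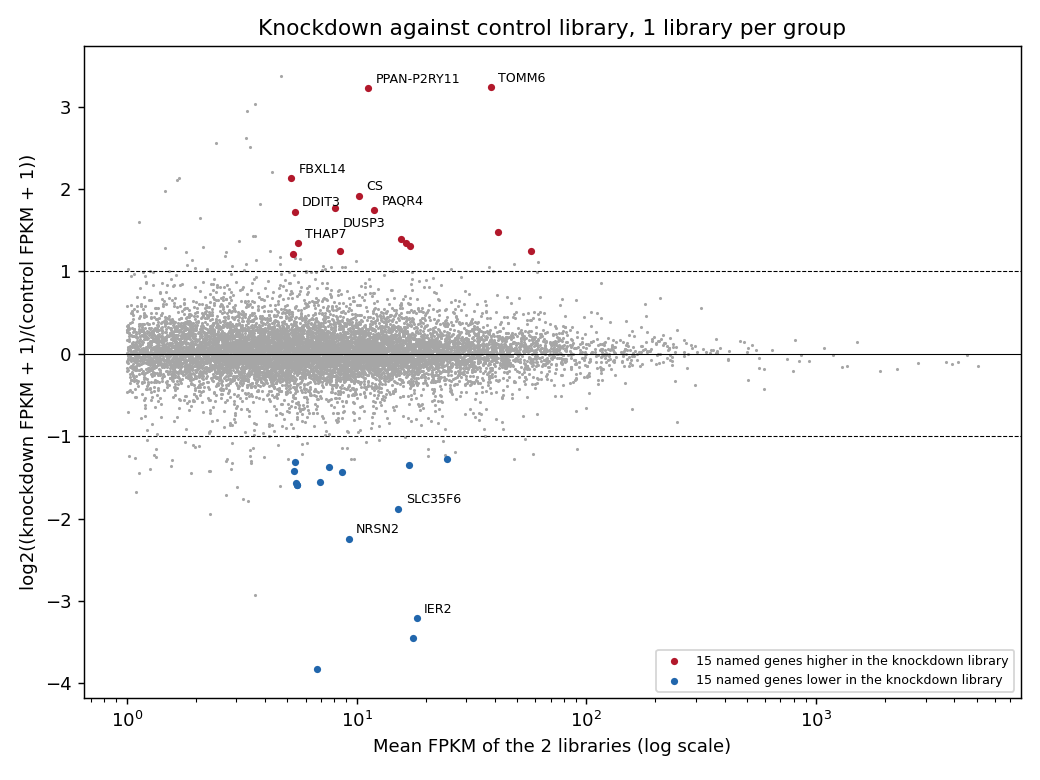
Log2 ratio of knockdown over control, from FPKM + 1, against the mean FPKM of the 2 libraries on a log scale, with 1 point per gene. Dashed lines mark 2-fold, and colours mark the 15 highest and 15 lowest named genes, among them TOMM6 at 3.24 and IER2 at -3.21.

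The third comparison asked whether groups of related genes lay together. Of 59 lists, 55 had at least 5 measured members, and 12 had a median outside the central 95 percent of their random lists. Of the 12, 6 lay above and 6 below. By chance 2.8 would be expected if the members of a list varied independently, like genes drawn at random. Related genes may vary together between cultures, and without replicate libraries the number expected in the absence of a knockdown is not known. The 12 against 2.8 is therefore no measure of an effect of the knockdown. At the central 99 percent, 7 lists lay outside.

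Genes of the ATF4 and amino acid response, which cells induce when amino acids run short or translation initiation is checked, were higher in the knockdown library. Their median log2 ratio was 0.19, at percentile 100 of random lists, and 27 of 36 members were above 0. Besides DDIT3, the largest ratios belonged to the glutamine transporter gene SLC1A5 at 81.2 against 40.3 FPKM, the glutathione-degrading enzyme gene CHAC1 at 2.34 against 0.780, and PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2, at 37.6 against 21.7. Mitochondrial ribosomal protein genes had a median of 0.11, at percentile 99.97, with 44 of 58 above 0. MRPL34 and MRPS34, at 258 against 161 FPKM, and MRPS2, at 16.9 against 10.3, were among the largest ratios, and MRPL10 went the other way at 3.33 against 7.66. Cytosolic ribosomal protein genes had a median of 0.08, at percentile 99.6, with 67 of 79 above 0, but lay inside the random range, at percentile 96.3, when random lists were matched also on the 3' UTR length of principal transcripts, a setting added after the data had been seen. Their median 3' UTR in those transcripts was 68 bases, and over all genes the ratio was higher where the 3' UTR was shorter, with a median of 0.06 in the fifth of genes whose longest annotated 3' UTR was shortest. Mitochondrial ribosomal protein genes stayed outside, at percentile 99.8. Among the largest ratios of the cytosolic genes were RPL36A at 38.7 against 23.0 FPKM, RPL3 at 217 against 142 and RPS13 at 44.3 against 29.1.

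Replication-dependent histone genes had the highest list median, 0.36 at percentile 99.99, with 10 of 14 measured members above 0. The largest ratios were H2AC8 at 4.66 against 1.81 FPKM, H2BC5 at 7.37 against 3.30, H2AC6 at 7.97 against 4.15 and H2AC13 at 1.78 against 0.763. These genes have near-identical copies among which reads may be divided, and their values are uncertain for that reason. Luminal breast epithelium markers had a median of 0.16, at percentile 99.4, with 15 of 19 above 0. That median lay inside the central 99 percent. Among them AGR2 was at 9.54 against 6.06 FPKM, ERBB2 at 6.61 against 4.14 and TBC1D9 at 6.07 against 3.97. XBP1, also an effector of the unfolded protein response, was at 65.5 against 46.3 FPKM. The list of endoplasmic reticulum chaperones and unfolded protein response genes, which also holds XBP1, lay inside the random range. Its median was -0.02 at percentile 20.1, with 15 of 26 below 0. Immediate early genes had a median of 0.17 at percentile 98.8, with 12 of 17 above 0, but their mean, IER2 included, was -0.09, and the median lay inside the random range in 7 of 17 alternatives. KLF6 was at 3.10 against 5.84 FPKM, ATF3 at 3.16 against 1.63 and MYC at 1.94 against 3.43.

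Genes of mitosis and G2/M were lower in the knockdown library, with a median of -0.15, at percentile 0 of random lists, and 37 of 45 members below 0. UBE2C, the E2 enzyme of the anaphase-promoting complex, was at 45.7 against 76.6 FPKM, the cytokinesis gene ANLN at 39.4 against 55.9, the mitotic kinase gene AURKA at 30.04 against 40.10 and ECT2 at 19.8 against 26.3. The proliferation marker MKI67, named here after its value had been seen, went the other way at 20.2 against 15.5 FPKM. Targets of NRF2, the regulator of the oxidative stress response, had a median of -0.15 at percentile 0.010, with 21 of 29 below 0. TXNRD1, which encodes thioredoxin reductase, was at 28.0 against 69.2 FPKM and the aldo-keto reductase gene AKR1B1 at 36.7 against 50.2, whereas CBR1 was at 40.5 against 26.4 and PRDX1 at 113 against 82.7.

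The 13 mitochondrially encoded genes were all below 0, with a median of -0.12 at percentile 0.41. The median became 0 under quantile normalization, the 1 of 15 alternatives that put this list inside the random range. That method gives genes of equal rank in both libraries the same value. The 0 therefore reflects their ranks and does not show whether the shift depends on scaling. MT-ND6 was at 107 against 125 FPKM, MT-ND5 at 1761 against 2034, MT-ND1 at 2103 against 2392 and MT-ND3 at 558 against 635. Only 243 genes had a mean of at least 100 FPKM, too few to fill the top bin of mean expression. The random lists for the mitochondrially encoded genes therefore held mostly less abundant genes. NOTCH genes had a median of -0.18 at percentile 1.0, with 6 of 9 below 0, and lay inside the random range in 4 of 17 alternatives; JAG1 was at 4.89 against 6.93 FPKM, NOTCH3 at 42.5 against 54.0, RBPJ at 4.29 against 5.61 and NOTCH1 at 2.815 against 3.474. Heat shock and chaperonin genes had a median of -0.07 at percentile 1.3, with 18 of 27 below 0, and lay inside the range in 2 of 17 alternatives; DNAJB1 was at 45.4 against 65.5 FPKM, CHORDC1 at 9.62 against 12.01 and HSPA4 at 71.03 against 85.31, while CRYAB was at 8.72 against 3.89. Glycolysis genes had a median of -0.09 at percentile 2.3, with 14 of 19 below 0, and lay inside the random range in 6 of 17 alternatives; SLC2A1 was at 9.66 against 14.1 FPKM and PFKP had a log2 ratio of -0.37, while PFKL was at 22.7 against 15.5 and SLC16A1 at 6.03 against 4.25.

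The type I interferon response, a common response to transfected nucleic acids, had a median of 0.005 at percentile 38.0, with 15 of 30 members above 0. The control cells were given si-NC, so a response present in both libraries would not show in this ratio. IFIT3 was at 1.61 against 2.60 FPKM, IFI6 at 2.57 against 1.63, DDX60 at 1.41 against 0.868 and IFITM2 at 7.05 against 9.24. Genes of DNA replication and G1/S had a median of -0.03 at percentile 10.4, with 18 of 41 above 0. The 4 largest ratios were below 0, with RRM2 at 24.4 against 47.0 FPKM, RFC3 at 10.99 against 17.83, UHRF1 at 14.4 against 23.0 and CCNE2 at 6.87 against 9.76. Targets of p53 had a median of -0.06 at percentile 9.6, with 11 of 27 above 0. PHLDA3 was at 7.82 against 17.3 FPKM, ZMAT3 at 0.586 against 2.11 and CDKN1A at 3.71 against 5.45, whereas TP53I3 was at 7.19 against 4.59. Apoptosis genes of the BCL2 family and their partners had a median of 0.01 at percentile 49.4, with 14 of 27 above 0. The pro-apoptotic BCL2L11 was at 5.723 against 1.496 FPKM, BCL2L2 at 4.83 against 8.59 and BIRC3 at 2.74 against 3.96.

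**Figure D2:**
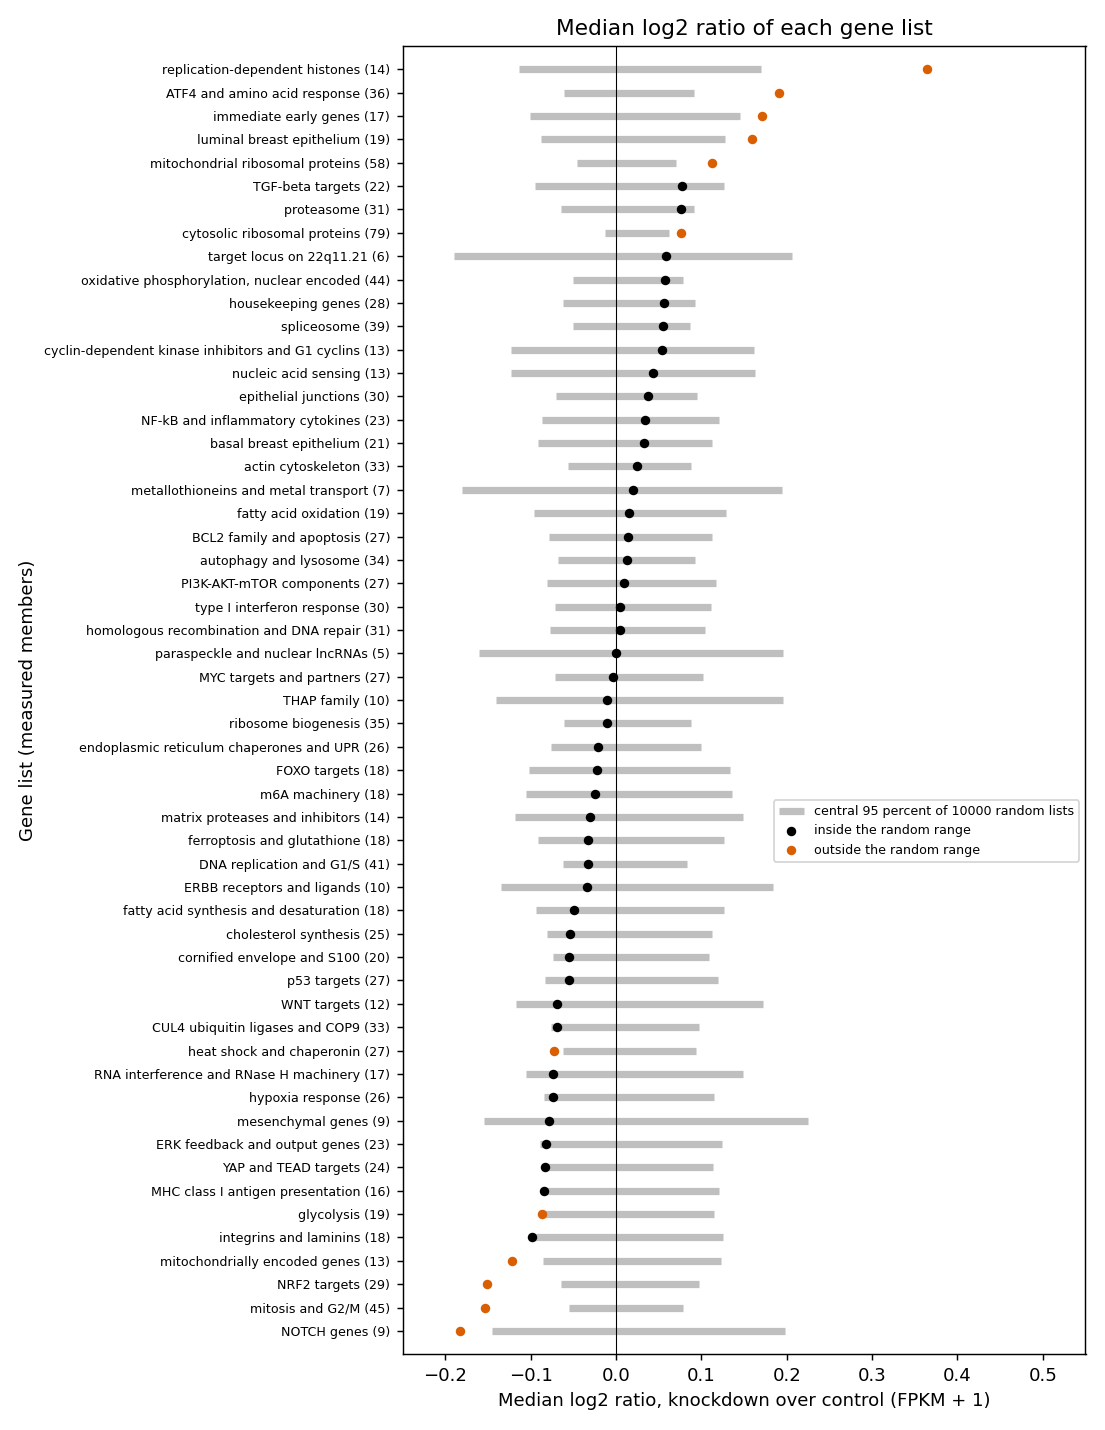
Median log2 ratio of knockdown over control, from FPKM + 1, for each of the 55 lists with at least 5 measured members, with the number of measured members in brackets. Grey bars span the central 95 percent of 10000 random lists matched on mean expression, and the 12 lists outside their bar run from NOTCH genes at -0.18 to replication-dependent histones at 0.36.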

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

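The settings that leave out genes sharing exons, or genes with 4 words of 7 bases, and those that match random lists also on 3' UTR length, were chosen after seeing the data, as was the second form of the word scan. THAP7-AS1 gave no value under any setting. The counts of genes at least 2-fold higher and lower, 66 and 73, became 140 and 126 with a pseudocount of 0.1, 19 and 14 with a pseudocount of 5, 31 and 36 with a mean of at least 5, 326 and 269 at 1.5-fold and 20 and 15 at 3-fold. By construction a stricter filter or fold takes fewer genes and a larger pseudocount shrinks the ratios of low genes; the cause of other differences was not tested. Without the 1642 genes sharing exons the counts were 39 and 45, and without the 3916 genes with the words 43 and 37, over fewer genes. The MAD-based SD of all genes, 0.21, was 0.13 with a pseudocount of 5. Centring, quantile normalization and rescaling without the 100 most abundant genes each gave 60 higher and 76 or 77 lower genes. The number of lists outside the central 95 percent ran from 10 to 13 over the alternatives, and 7 lay outside the central 99 percent, a stricter limit. Of the 12 lists, 5 lay outside under every alternative that gave a value: ATF4 and amino acid response, mitochondrial ribosomal proteins, histones, mitosis and G2/M and NRF2 targets. Mitochondrially encoded genes lay inside under quantile normalization, which sets values by rank and so cannot show a shift between genes of equal rank. Matching on the longest annotated 3' UTR left outside 11 of the 11 lists with a value, and matching on that of principal transcripts 10 of 11, with cytosolic ribosomal proteins inside at percentile 96.3; only 8 histone genes had a 3' UTR, with a median of 0.62. Conversely, 9 lists inside the range lay below it in some alternatives: YAP and TEAD targets in 6, MHC class I genes in 4, ERK feedback, integrins and laminins and cornified envelope genes in 3 each, and WNT targets, RNA interference, fatty acid synthesis and ferroptosis genes in 1 each. Immediate early genes, with a median of 0.17, had -0.092 when the mean replaced the median. Of 828 values of the 138 genes named in the text under another pseudocount or scaling, 736 moved by less than the MAD-based SD of genes at their level and 92 by more; 1 changed sign, that of CD68, from 0.017 to -0.0074 under quantile normalization. Depth limits low genes most, and with 1 library per group no alternative measures the spread between cultures.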

Other observations

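Some other gene groups held single genes that stood apart while their medians lay inside the random range. Among autophagy and lysosome genes, with a median of 0.01 at percentile 49.95, the ATG8-family gene GABARAPL1 was at 6.83 FPKM in the knockdown library against 2.49 in the control library and the kinase gene ULK1 at 5.06 against 2.85, whereas NEU1 was at 7.17 against 10.3. Genes of the RNA interference and RNase H machinery had a median of -0.07 at percentile 7.2 and 10 of 17 below 0, with DICER1 at 4.98 against 9.62, TNRC6A at 3.55 against 6.38, PRKRA at 7.93 against 11.7 and AGO2 at 6.90 against 9.44. The mean of that list lay at percentile 1.66, outside the range. Among matrix proteases and inhibitors, with a median of -0.03 at percentile 26.1, TIMP2 was at 5.10 against 13.8, PLAU at 4.80 against 10.4, PLAUR at 6.36 against 8.10 and ADAM15 at 14.004 against 5.879. The receptor gene EGFR, abundant in both libraries, was at 258 against 336 FPKM. YAP1 was at 26.4 against 13.7, ANKRD1 at 6.22 against 4.24, CCN1 at 15.3 against 11.1 and ASAP1 at 8.003 against 11.02, and 16 of 24 measured YAP and TEAD genes were below 0, with a median of -0.08 at percentile 2.55, just inside the range, and outside it in 6 alternatives.

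The 4 lists of markers of other cell types had fewer than 5 measured members each, so no median or rank was computed for them. The fibroblast list had 3 measured members (C1R at 1.92 against 1.23 FPKM, FAP at 0.859 against 1.37, FBLN1 at 40.4 against 47.4) and the leukocyte list 4 (CD14 at 10.3 against 9.50, LYZ at 1.25 against 1.39, CORO1A at 2.28 against 2.45, CD68 at 3.30 against 3.25). The endothelial list had 2 (KDR at 1.07 against 1.15, EGFL7 at 4.84 against 4.73), and of other lineages ALB was at 9.42 against 11.6, APOA2 at 11.98 against 13.70 and APOA1 at 1.32 against 1.15.

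A scan of 15715 words of 7 bases in the 3' UTRs of 10718 genes was undertaken, and its settings chosen, after the lowest genes had been seen; it related each word to the log2 ratio, clipped at 1.5, after allowing for 3' UTR and coding length, GC content and mean expression. Also chosen after the result was seen were the tests against words of equal composition, the bound from shuffled ratios that they use, and those of all 3' UTR words against coding sequence, and, further on, those with random partners of genes that share exons. Differences carry SEs over genes, which are not replicate errors, and neighbouring words overlap. The lowest word was CTCATTA, whose 1119 genes were lower by a mean of -0.071 ± 0.009, and the highest CGGAGAA, whose 262 genes were higher by 0.115 ± 0.018. Both SEs use the SD of all genes. Their own SEs, from the separate spreads of genes with and without the word, were 0.009 and 0.022. An earlier form of the scan, with a mean of at least 2 FPKM and no coding terms, gave -0.074 and 0.124; CTCATTA was again lowest, and GGAGAAA highest with CGGAGAA next. THAP7-AS1 holds 16.2% of all words, 5 of the 10 lowest and 6 of the 10 highest, CTCATTA and CGGAGAA both included, so that this does not separate the ends.

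Base composition as the cause is argued against for CTCATTA and, less firmly, for CGGAGAA. Of 100 random splits of 9148 genes, CTCATTA was the lowest word of the picking part in 77 and CGGAGAA the highest in 40. Where CGGAGAA was not the highest, GGAGAAA often was. Some other highest words fell near 0 in the other part, such as TGCTCGA at 0.004 from its composition. In the splits that picked them, CTCATTA and CGGAGAA lay -0.070 and 0.094 from the mean of words of their composition in the other part (medians). The SEs were 0.013 and 0.026, and the SDs of those words 0.013 and 0.021. Over all genes they lay -7.45 and 4.87 of their own SEs from that mean, beyond the -4.61 and 4.41 that any word reached in 100 shuffles of the ratios over genes (-4.39 and 4.58 in a first form with pooled SEs); the verdict on CGGAGAA turns on this bound, which replaced, after these values had been seen, a rule that a word be picked in most splits and that had left composition open for it. Seed pairing, by which a short guide RNA silences transcripts that match a few of its bases, may account for both. The guide would be a silencing oligonucleotide for the lower genes and an oligonucleotide in the control library for the higher genes. Genes with 8 matching bases differed from those with 7 by -0.073 ± 0.017 and by 0.138 ± 0.044. The 8-base words join 7-base words that the scan had ranked as extreme in these same genes. That choice favoured such differences, so no conclusion is drawn from them. Seed pairing stays open. The words in coding sequence had differences of -0.032 ± 0.010 and 0.043 ± 0.009. These were not clearly smaller than -0.035 ± 0.007 and 0.050 ± 0.027 for 7 bases in the 3' UTR. The groups are unlike, however, because that 3' UTR group left out genes with 8 bases and the coding group did not. With all 3' UTR words pooled, which removes this inequality, the difference from coding sequence was -0.020 ± 0.012 and 0.077 ± 0.024. The coding difference was thus smaller for CGGAGAA, well beyond the SE, and not clearly smaller for CTCATTA. Both words had been picked as extreme in the 3' UTRs of these same genes. That choice favours larger differences there, so the question is not decided. For CTCATTA, release of an annotated microRNA with the same seed cannot be told apart from seed pairing of an oligonucleotide. Its reverse complement TAATGAG is held by 6 annotated hairpins, against a median of 7 for other words of that composition. The word was sought anywhere in a hairpin, so these hairpins are not shown to carry a microRNA with that seed. No such search was made for CGGAGAA. The knockdown itself also stays open, and the oligonucleotide sequences were not used here.

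Genes with longer 3' UTRs, by their longest annotated one, had lower ratios in the knockdown library, with a rank correlation across genes of -0.153. The median log2 ratio was 0.06 in the fifth of genes with the shortest 3' UTRs and -0.02 in the fifth with the longest. Sites of the 20 words at both ends of the scan are argued against as the whole cause. The correlation was -0.147 among 2767 genes with none of these words. Those genes may hold seed sites of other words, so seed sites in general stay open. GC content of the 3' UTR as the whole cause is argued against too, with -0.134 once GC was allowed for. RNA quality and the knockdown itself were not tested and stay open.

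Many of the genes at least 2-fold apart share exons with another gene on the same strand: 55 of 139, or 39.6%, against 15.1% of all genes and 10.1% to 22.3% in random sets matched on expression; some readthrough genes had been seen before this share was computed. A candidate explanation is that reads were divided differently between overlapping genes in the 2 libraries. For 33 of 44 such genes with listed partners, the partners' summed FPKM differed in the opposite direction, against 16 to 29 with random partners of like expression. Some pairs, such as TOMM6 and ENSG00000124593, entered from both sides, some in opposite directions and some in the same. The 44 are therefore not separate cases. Random partners need not mirror each other in this way, so the 2 counts are not strictly alike. Summing a gene with its partners does not decide it, because 33 of the 44 came under 2-fold with their own partners and a median of 31, from 27 to 33, with random ones. TOMM6, CS, C7orf25 and SLC35F6 stayed at least 2-fold apart after summing. The explanation stays open, as does a change in which of the overlapping transcripts the cells made, which was not tested.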
